A study of Homo sapiens with 2 samples.

How the data were processed

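Transcript levels were measured by RNA sequencing in 2 libraries of human testis total RNA, a commercial preparation, which are called testis 1 and testis 2 here after the numbers in their titles. Per the labels' protocols, a small amount of unfractionated RNA was reverse transcribed, the cDNA was amplified with an RNA amplification kit, and libraries were built from the amplified cDNA and read as paired reads of 51 bases on an Illumina instrument. The protocol text also describes the isolation of sperm RNA, which does not concern a purchased testis RNA. Nothing in the labels says that the libraries came from separate donors or separate lots, so a spread between them measures only the difference between these libraries, which may be purely technical. The strand setting of the counting and the way reads with several genomic matches were treated are not given in the sources used here.

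The values deposited by the authors are FPKM per the file headers, 1 value per gene and library. FPKM stands for fragments per kilobase, scaled to a total that the headers do not define. The name of the table says RPKM, and the design fixed beforehand assumed that unit; the analysis is the same for both. CASAVA 1.8.2 and the genome build hg19 are named in the submitters' processing notes. The aligner, the counting program, the gene models and any filter are not given in the sources used here. The table has 23180 genes, each with an NCBI gene number and a symbol. Of these numbers, 22392 matched a current NCBI gene record, which gave gene type and chromosome (the record's assembly is GRCh38, so none of its coordinates were used). Coordinates printed for genes are those of GENCODE release 44 mapped to GRCh37, the assembly that hg19 names, and were looked up by symbol. Spreadsheet software had turned 28 symbols into dates, and these were restored through the gene number. Because the RNA is human, 104 genes (Y-linked genes and XIST) were left out of every step, and 23076 genes were analysed.

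FPKM values are not counts, so no count test was used. With 1 group of 2 libraries there is no comparison between groups and no p-value is given. Values are means ± SD over the 2 libraries (n = 2). The SDs of levels are those of values as deposited, so they include the general difference in level between the libraries. A small SD therefore does not show close agreement after scaling. The log scale is log2(FPKM + 1), a pseudocount of 1 FPKM, which understates differences of genes near or below 1 FPKM.

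Depth was estimated from the low values. In genes with 1 annotated transcript shorter than 2.5 kb and with less than 0.5 FPKM, the product of FPKM and transcript length fell on whole multiples of a constant, the worth of 1 read. This put the normalising totals at about 18600000 reads for testis 1 and 11800000 for testis 2. Whether the steps stand for single mates or for fragments is not known: of these values, those within 0.1 reads of 2 steps numbered 92 in testis 1 and those of 1 step 58, and in testis 2, 86 and 155. If mates were counted separately in testis 1, its total in fragments, the ratio of the totals and the limits below would differ. Within a tolerance of 0.1 reads, 60.7% of 529 values and 64.2% of 595 values were whole. Chance gives 20% for a total fixed beforehand. The totals were fitted to these same values, so the shares are no independent check. The ratio of the totals was 1.57, and the ratio between the libraries' values of low genes gave 1.57 without transcript lengths. Both estimators were settled after looking at the values: a first estimate used a cosine score (rounded, 18600000 and 11800000 when repeated) and was replaced by the count of values close to whole reads, and the tolerance of the length-free ratio was narrowed after a first result. At a length of 1.5 kb, 1 read is worth 0.0358 FPKM in testis 1 and 0.0564 FPKM in testis 2, and 3 reads, the limit that a count of 0 allows, 0.108 and 0.169 FPKM. These limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A value of 0 is described as listed at 0. The transcript lengths are those of GENCODE and may differ from the authors' gene models.

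Before the data were examined, 23 gene lists (germ cell stages, somatic cell types, accessory glands, other tissues, ribosomal proteins and others), 33 pairs of a germline and a somatic paralog, the rule for naming genes and the alternatives were fixed. One list, the 13 mitochondrially encoded mRNAs, was not analysed here, which leaves 22 lists with 432 different genes, 5 of them in more than 1 list. The level of a list is the median FPKM of its members. Its percentile is its place among 10000 random lists of the same size drawn from all genes of that library, which describes these libraries and is not a p-value. Random draws were first taken from a single stream, under which 2 runs disagreed on a list close to the 95th percentile; each list was then given its own seed, a choice made after that disagreement was seen, and 20 further sets of draws were taken. For the difference between libraries, the median log2 difference of a list (testis 2 minus testis 1) was placed among 10000 random lists of the same size matched on mean level in 20 bins. A paralog pair was called larger than the spread between libraries when its log2 ratio had the same sign in both libraries and a mean above a threshold. That threshold was the root of the summed squares of 2 values, 1 per member, each the 95th percentile of the absolute between-library difference (after subtraction of the median difference of genes with a mean of at least 1 FPKM) over the 200 genes nearest in level. The genes named are the 15 protein-coding genes with the highest mean FPKM other than ribosomal proteins, the 3 highest members of each list and the lowest member of a list described as present throughout, the 4 paralog pairs at either end of the ratios, and the 5 genes with the largest difference in each direction among those with a mean of at least 10 FPKM. Where annotated exons of named genes overlap another gene (such as DNMT1 with S1PR2, SPATA22 with TRPV3, TAGLN with PCSK7, CCNA2 with EXOSC9 and EEF1A1 with MTO1), reads of both may be included, since use of strand is not stated. A few genes that this rule selects are not reported here by name. Genes whose values are given outside this rule were chosen after the values were seen.

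Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data. Read counts were drawn with Poisson error only, at a fixed gene length, for the 23076 genes at their real mean levels. All of the 105 simulated genes with a 4-fold change and a mean of at least 5 FPKM were recovered (100%). Changed genes with a mean between 1 and 5 FPKM were simulated too, but their recovery was not measured. At the limit of 1 FPKM there were 0 calls of a 2-fold difference among unchanged genes. The real spread between the libraries was larger than Poisson error, so that 0 does not measure false calls in the real data. Of 200 simulated lists of randomly chosen genes without a shift, 5% lay outside the central 95% of the random lists. A share near this follows from how the lists were drawn. It does not show how real lists behave, whose members may vary together. Alternatives were pseudocounts of 0.1 and 0.01 FPKM, other limits on low values, scaling of the libraries to equal sums or to a median difference of 0, averaging of rows with the same symbol, random lists drawn only from genes above 0, and each library alone. Corrections for GC content and transcript length, and counts without the MTRNR2L genes, were added after the data were seen.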

Results

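Human testis RNA was sequenced in a series on the proteins and transcripts of human semen. The 2 libraries of the single group, testis, were prepared from commercial total RNA, and no second group was compared. FPKM values summed to 228468 over 23076 genes in testis 1 and to 197762 in testis 2. The estimated normalising totals were 18600000 and 11800000 reads, and whether they hold only reads counted on genes is not known. An FPKM of at least 1 was reached by 14752 genes in testis 1 and 14234 in testis 2, and by 13783 genes in both (59.7%). In both libraries 4165 genes reached 10 FPKM, 205 reached 100 FPKM and 5 reached 1000 FPKM. Among protein-coding genes 12470 of 18912 reached 1 FPKM in both libraries (65.9%), and among long non-coding RNA genes 716 of 2356 (30.4%).

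The most abundant protein-coding transcripts included genes of spermatid chromatin and widely expressed genes. PRM1 (gene 5619) had the highest level, 2357 ± 176 FPKM (SD, n = 2), and PRM2 reached 1315 ± 166 FPKM. Both encode protamines, the small basic proteins that replace histones in sperm chromatin, and lie next to each other on chromosome 16 (hg19, 11374698 to 11375187 for PRM1 and 11369496 to 11370337 for PRM2). TNP1, a transition protein of the same exchange (chromosome 2, 217724181 to 217724787), stood at 767 ± 66.6 FPKM, and HIST1H2AA, a testis histone gene (chromosome 6, 25723625 to 25726790), at 930 ± 36.9 FPKM. CLU, which encodes the secreted chaperone clusterin (chromosome 8, 27454434 to 27472217), reached 1795 ± 124 FPKM, and PTGDS, a prostaglandin D synthase, 511 ± 13.3 FPKM. CMTM2 reached 1040 ± 346 FPKM and PHF7, a zinc finger gene of the male germ line, 787 ± 89.8 FPKM. The other genes among the 15 highest were the elongation factor EEF2 with 1214 ± 129 FPKM, TMSB10 with 892 ± 23.8, the cytoplasmic actin ACTG1 with 827 ± 27.2, the glutamine synthetase GLUL with 821 ± 98.1, the ubiquitin gene UBB with 607 ± 114, BSG with 523 ± 0.457 and PABPC1 with 515 ± 25.5 FPKM. These 15 genes held 6.81% of the summed FPKM of testis 1 and 7.203% of that of testis 2.

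Lists of marker genes were used to describe the levels of genes linked to the germ cell stages. A list median in whole tissue RNA does not show which cells the transcripts came from, since members may be expressed elsewhere too. Genes of chromatin condensation in spermatids had the highest median of the 22 lists, 119 ± 12.5 FPKM (SD, n = 2), and 6 of their 12 members exceeded 100 FPKM in both libraries. The lowest member, HILS1, named after its value was seen, had 1.54 FPKM in testis 1 and 0.998 FPKM in testis 2. Genes of the sperm flagellum had a median of 16.2 ± 0.818 FPKM, and all 36 reached 1 FPKM in both libraries. SMCP, a cysteine-rich protein of the mitochondrial capsule, led them with 226 ± 57.4 FPKM, followed by ODF2, of the outer dense fibres, with 164 ± 4.44 FPKM and ROPN1B with 154 ± 30.3 FPKM. ROPN1B has a close paralog, ROPN1, with which it could share reads. The lowest member, FSIP1, had 2.43 FPKM in testis 1 and 2.49 FPKM in testis 2. All 24 acrosome and sperm-egg interaction genes reached 1 FPKM as well, with a median of 13.8 ± 1.74 FPKM. ACRBP, the binding protein of proacrosin, stood at 218 ± 35.6 FPKM, CRISP2 at 78.8 ± 27.1 FPKM and ACR, proacrosin itself, at 58.9 ± 1.82 FPKM, and SPAM1, a sperm hyaluronidase, was lowest by mean with 2.76 and 1.16 FPKM. Sperm ion transport genes had a lower median, 6.45 ± 0.0481 FPKM, and were led by the calcium pump ATP2B4 with 61.7 ± 12.6 FPKM, CATSPERG, a subunit of the sperm calcium channel, with 37.6 ± 18.6 FPKM, and the anion transporter SLC26A8 with 26.4 ± 2.96 FPKM.

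Meiotic and piRNA genes were present at intermediate levels, and spermatogonial genes at low ones. The 28 meiotic spermatocyte genes had a median of 10.7 ± 2.48 FPKM, and 25 reached 1 FPKM in both libraries. SPATA22, required for meiotic recombination, had 75.2 ± 15.3 FPKM, the germ cell cyclin CCNA1 54.0 ± 6.23 FPKM and the meiotic cohesin subunit STAG3 48.3 ± 0.758 FPKM. All 18 genes of the piRNA pathway, which silences transposons in germ cells, reached 1 FPKM, with a median of 10.03 ± 2.22 FPKM. GTSF1 had 93.5 ± 24.9 FPKM, MAEL 76.6 ± 10.1 FPKM and PIWIL1 55.1 ± 13.8 FPKM, and ASZ1 was lowest with 3.21 and 1.01 FPKM. The median of the undifferentiated spermatogonia list was 2.98 ± 0.131 FPKM, led by FMR1NB with 11.6 ± 0.525 FPKM, ZBTB16, a transcription factor of spermatogonial stem cells, with 10.2 ± 0.268 FPKM and PHGDH with 7.34 ± 1.77 FPKM. The differentiating spermatogonia list had a median of 3.59 ± 0.171 FPKM, with the DNA methyltransferase DNMT1, also present in other dividing cells, at 90.02 ± 6.13 FPKM, SOHLH2 at 20.5 ± 1.97 FPKM and DMRTB1 at 19.3 ± 0.779 FPKM. SOHLH2 shares exons with an annotated read-through transcript. Against random lists, the spermatid chromatin, flagellum, acrosome, meiotic, piRNA and ion transport lists lay above the 95th percentile in both libraries, the last at 95.2 in testis 1 and 97.3 in testis 2. That call of the ion transport list depended on the random draw: in 20 further sets of draws, 11 of the 22 lists lay above the 95th percentile in 15 sets and 12 lists in 5 sets. With only genes of at least 1 FPKM, the piRNA list (96.1 and 92.1) and the ion transport list (71.7 and 74.7) no longer lay above it in both libraries. The undifferentiated spermatogonia list lay at percentiles 63.6 and 76.7 and the differentiating one at 71.2 and 74.9. Medians of all post-meiotic lists named here exceeded those of both spermatogonial lists in each library.

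**Figure D1:**
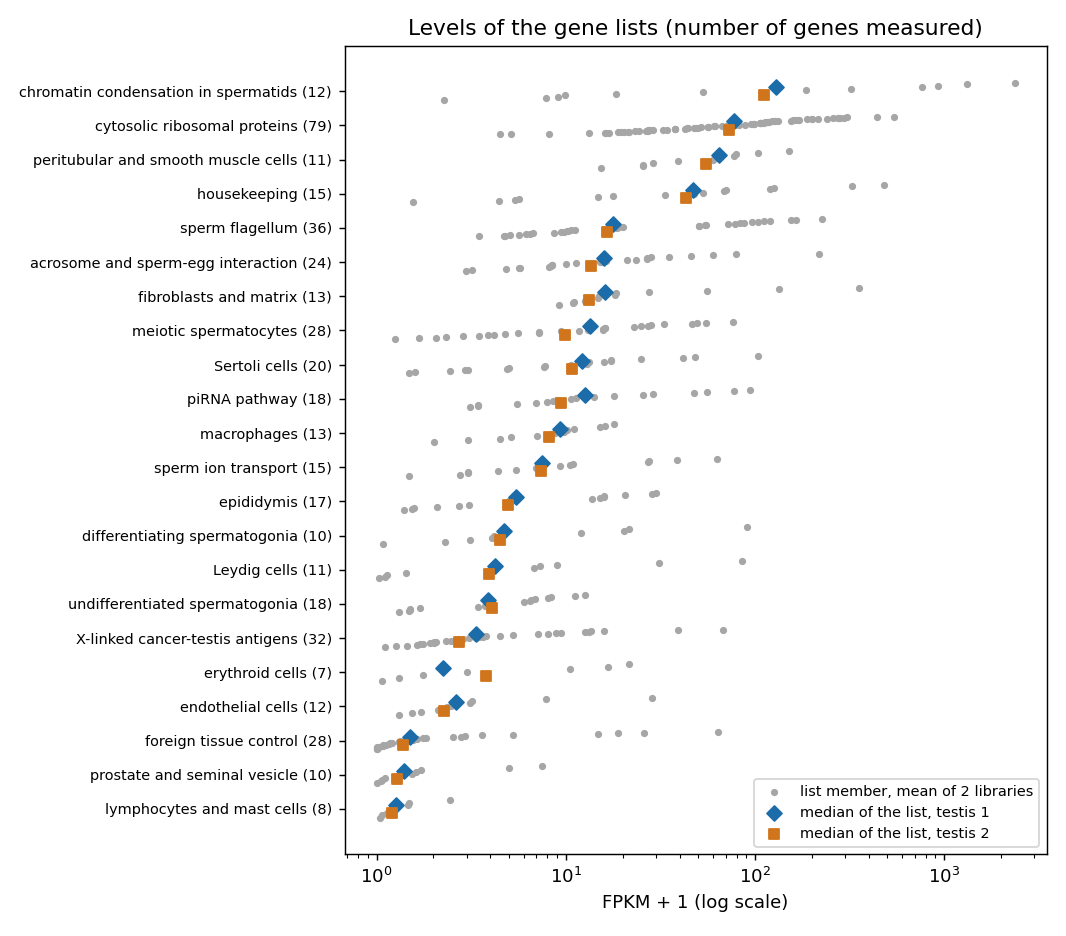
Levels of the 22 gene lists. The horizontal axis is FPKM + 1 on a log scale, grey points are list members (mean of both libraries), diamonds the list median in testis 1 and squares that in testis 2, with the number of genes measured in parentheses. Chromatin condensation genes of spermatids have the highest median (119 FPKM) and markers of lymphocytes and mast cells the lowest (0.237 FPKM).

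Of the lists of somatic cell types, those of contractile, matrix and Sertoli cell genes had the highest medians. Which cells or attached tissue these transcripts came from was not tested. The 11 peritubular and smooth muscle genes had a median of 58.8 ± 6.71 FPKM (SD, n = 2), and all exceeded 10 FPKM in both libraries. TAGLN, an actin-binding protein of smooth muscle, stood at 150 ± 2.13 FPKM, the smooth muscle actin ACTA2 at 103 ± 47.2 FPKM and desmin, DES, at 78.4 ± 20.1 FPKM, and ACTG2 was lowest with 14.6 and 14.02 FPKM. All 13 fibroblast and matrix genes reached 1 FPKM, with a median of 13.7 ± 2.05 FPKM, led by SPARC with 353 ± 24.1 FPKM, DCN with 132 ± 23.8 FPKM and the collagen gene COL1A2 with 55.0 ± 1.79 FPKM, while COL6A1 was lowest with 8.75 and 7.66 FPKM. Sertoli cell genes had a median of 10.48 ± 1.01 FPKM, and 18 of 20 reached 1 FPKM in both libraries. CLDN11, a tight junction protein of the blood-testis barrier, stood at 103 ± 3.17 FPKM, PRND at 47.4 ± 6.68 FPKM and DEFB119 at 40.5 ± 0.1005 FPKM. Leydig cell genes had a median of only 3.10 ± 0.210 FPKM over 11 genes, although INSL3, a hormone of these cells, reached 84.0 ± 1.58 FPKM, STAR, the cholesterol carrier of steroid synthesis, 30.1 ± 3.02 FPKM and HSD17B3 8.02 ± 1.36 FPKM. The 3-beta-hydroxysteroid dehydrogenase gene HSD3B2, named after its value was seen, had 0.231 FPKM in testis 1 and was listed at 0 in testis 2. The Sertoli, smooth muscle and matrix lists lay above the 95th percentile of random lists in both libraries, and the Leydig list at percentiles 66.8 and 70.1.

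Markers of blood and vessel cells ranged from intermediate to low levels. Macrophage genes had a median of 7.74 ± 0.766 FPKM (percentiles 97.4 and 97.6, and 75.99 and 78.7 with only genes of at least 1 FPKM), with HLA-DRA at 16.97 ± 7.58 FPKM and the complement genes C1QC at 15.1 ± 2.14 FPKM and C1QA at 14.2 ± 0.485 FPKM, and 12 of 13 reached 1 FPKM in both libraries. The median of 12 endothelial genes was 1.46 ± 0.245 FPKM (30.05 and 27.4), with ENG at 27.4 ± 2.02 FPKM, VWF at 6.87 ± 0.776 FPKM and ESAM at 2.18 ± 0.333 FPKM. Lymphocyte and mast cell genes had a median of 0.237 ± 0.0497 FPKM (1.64 and 1.09), and of 8 genes only TPSAB1 reached 1 FPKM in both libraries, with 1.52 FPKM in testis 1 and 1.38 FPKM in testis 2, ahead of CPA3 with 0.478 ± 0.0197 FPKM and CD2 with 0.469 ± 0.0193 FPKM. In the erythroid list the haemoglobin genes HBB, HBA2 and HBA1 had 20.6 ± 4.74, 15.7 ± 3.64 and 9.49 ± 1.29 FPKM, HBA1 and HBA2 being near-identical copies whose reads cannot be told apart with certainty, and the list median was 2.02 ± 1.11 FPKM over 7 genes (28.2 and 64.3).

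Because the series concerns semen, markers of the ducts and glands that add to it were examined too. Epididymal genes had a median of 4.18 ± 0.362 FPKM (SD, n = 2), 14 of 17 reached 1 FPKM and 7 reached 10 FPKM in both libraries. Their list lay at percentiles 85.5 and 87.2, and at 87.8 and 82.8 with only genes of at least 1 FPKM. The near-identical neighbours SPAG11B and SPAG11A had 28.9 ± 4.94 and 27.6 ± 1.83 FPKM, and ADAM7, a membrane protein of the epididymis, 19.6 ± 4.44 FPKM. Prostate and seminal vesicle genes had a median of 0.341 ± 0.0840 FPKM and lay below the 5th percentile of random lists in both libraries (2.41 and 1.86), but not with only genes of at least 1 FPKM, which leaves 2 of them (35.5 and 34.9). Among their members were the prostate protease KLK2 with 3.99 ± 0.296 FPKM and MSMB with 0.727 ± 0.423 FPKM. The semenogelin genes SEMG1 and SEMG2, named after their values were seen, encode the main proteins of the semen coagulum. SEMG1 had 0.0646 and 0.0667 FPKM, and SEMG2 had 0.108 FPKM in testis 1 and was listed at 0 in testis 2, levels of a few reads at most for a transcript of 1.5 kb. A control list of 28 genes of liver, muscle, brain, pancreas, skin, lung and kidney had a median of 0.443 ± 0.0880 FPKM, at percentiles 0.44 and 0.13, and at 36.6 and 23.7 for the 9 members with a mean of at least 1 FPKM. It held exceptions: APOA1, the apolipoprotein of high-density lipoprotein, stood at 63.2 ± 1.71 FPKM, the muscle genes MYL2 at 24.9 ± 1.90 FPKM and CKM at 17.9 ± 0.663 FPKM.

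General cellular transcripts were abundant. The 79 ribosomal protein genes of the cytosol had a median of 74.0 ± 3.51 FPKM, with RPL37A at 544 ± 107 FPKM, RPL38 at 443 ± 21.8 FPKM and RPS6 at 306 ± 87.0 FPKM, and held 3.68% and 3.99% of the summed FPKM. Many of these genes have processed pseudogenes that can take up their reads. The 15 housekeeping genes had a median of 44.3 ± 2.58 FPKM, among them ACTB with 479 ± 20.04 FPKM and EEF1A1 with 125 ± 39.6 FPKM.

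The paralog pairs asked whether a germline copy exceeds its somatic relative within the same RNA. Of 33 pairs, the germline gene was higher by more than the spread between libraries in 12, the somatic gene in 11, and 10 lay within that spread. The germline cyclin CCNA1 exceeded CCNA2 (2.91 ± 0.660 FPKM) 14.1-fold, at a log2 ratio of 3.82 ± 0.0808 (SD, n = 2) against a threshold of 1.06. The intronless glycerol kinase GK2 (14.1 ± 3.72 FPKM) exceeded GK, at 0.402 ± 0.126 FPKM, 10.7-fold. PIWIL1 exceeded the Argonaute gene AGO2 (4.22 ± 0.293 FPKM) 10.6-fold, and the testis calcineurin subunit PPP3R2 (52.4 ± 4.88 FPKM) exceeded PPP3R1 (6.04 ± 2.63 FPKM) 7.85-fold. At the other end, ACTB exceeded the actin-like gene ACTL7B (19.9 ± 0.716 FPKM), at a log2 ratio of germline to somatic gene of -4.52 ± 0.0107, and ACTL7A (72.8 ± 2.76 FPKM) 6.51-fold. The chaperone CALR (115 ± 10.9 FPKM) exceeded CALR3 (16.4 ± 0.167 FPKM) 6.65-fold. Among glycolytic pairs, named after their values were seen, PGK2 exceeded PGK1 5.04-fold and LDHC exceeded LDHA 2.36-fold, whereas the ratio of GAPDHS to GAPDH, 0.651, lay within the spread. All folds are on the FPKM + 1 scale, and reads shared between close copies could move them. A bias particular to a gene and common to both libraries would not enter the threshold, so the calls do not cover it.

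**Figure D2:**
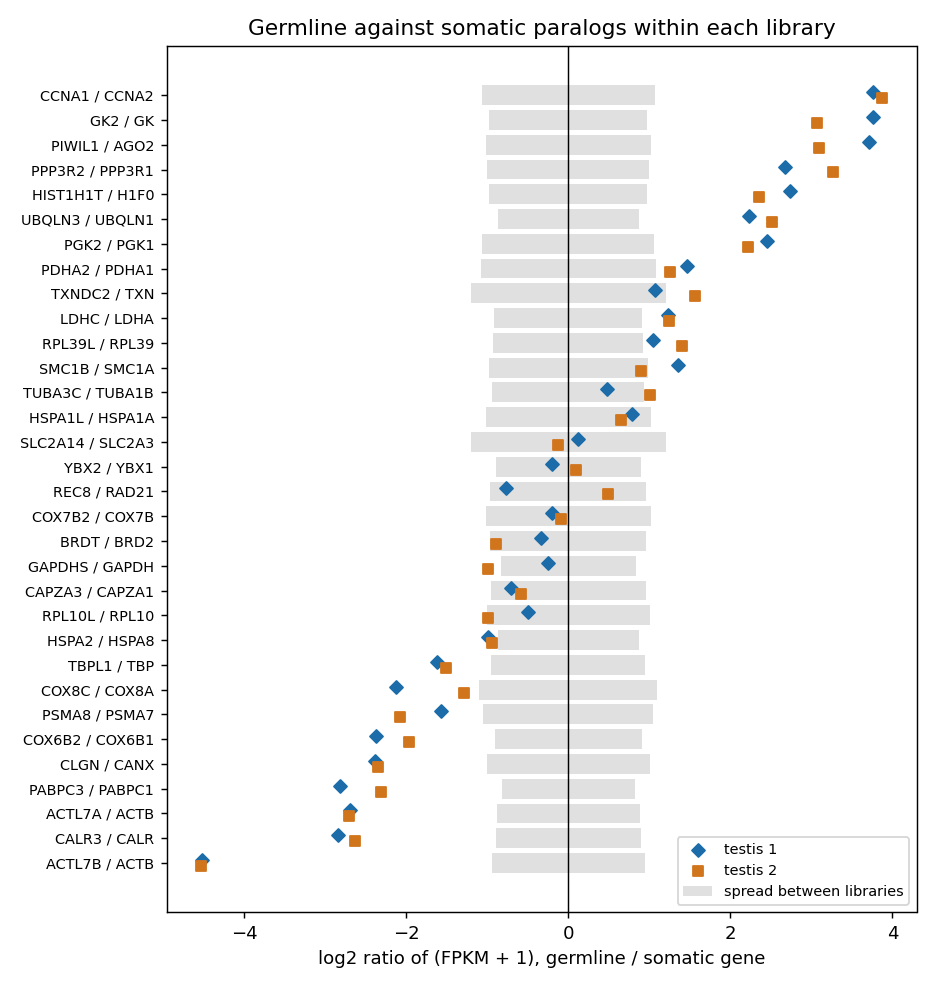
Germline against somatic paralogs. The horizontal axis is the log2 ratio of (FPKM + 1) of the germline to the somatic gene, diamonds are testis 1, squares testis 2, and grey bars span the threshold set by the spread between libraries on either side of 0. Of the pairs drawn, the mean of both libraries lies beyond the bar towards the germline gene in 12 and towards the somatic gene in 10, and 1 further pair is not drawn.

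Genes on the X chromosome were lower than autosomal genes. Among genes with a mean of at least 1 FPKM, the median was 4.15 FPKM for 504 X-linked genes and 6.13 FPKM for 13909 autosomal genes in testis 1, and 3.68 against 5.23 FPKM in testis 2. The ratio was 0.691 ± 0.0189 (SD, n = 2), an SD between libraries and not among chromosomes. The X chromosome had the lowest median of all chromosomes compared in both libraries, but some autosomes were close. The next lowest median was 4.48 FPKM for chromosome 4 in testis 1 and 3.83 FPKM for chromosome 13 in testis 2. The share of genes reaching 1 FPKM in both libraries was 51.5% on the X chromosome and lower, 46.8%, on chromosome 21. At least 10 FPKM was reached by 12.2% of X-linked and 22.8% of autosomal genes in testis 1, and by 10.51% and 19.8% in testis 2. X-linked cancer-testis antigens had a median of 2.04 ± 0.456 FPKM over 32 genes, with TKTL1 at 67.1 ± 0.627 FPKM, SPANXC with 37.4 and 38.7 FPKM in testis 1 and testis 2, and PAGE5 with 16.2 and 13.8 FPKM. SPANXC belongs to a family of near-identical copies, so its own share is uncertain.

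The 2 libraries were compared to see how far their values differ, whether or not they were made from the same lot of RNA. Across genes, which are not independent replicates, log2(FPKM + 1) correlated with Pearson's r = 0.980 and FPKM with Spearman's rho = 0.973. Among the 14585 genes with a mean of at least 1 FPKM, testis 2 was lower by a median of 0.18 on the log2 scale (median -0.18), with an SD of 0.39. As deposited, 97.49% of these genes differed by less than 2-fold. At least 2-fold differences were found for 366 genes, of which 76 were higher and 290 lower in testis 2. Once the median difference was subtracted, 273 genes differed at least 2-fold, not all of them among the 366, with 146 higher and 127 lower, so the split depended on the scaling. In 77 genes with 1 annotated transcript and at least 1000 estimated reads in testis 1, the between-library spread was 3.91 times its Poisson error. That limit was chosen after the values were seen, and the minimum in testis 2 was lower.

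Among genes with a mean of at least 10 FPKM, the 5 furthest above their level in testis 1 were MTRNR2L genes, nuclear loci that resemble the mitochondrial 16S ribosomal RNA gene. MTRNR2L10 (X chromosome, 55207824 to 55208944) had 4.94 FPKM in testis 1 and 57.3 FPKM in testis 2, a log2 difference of 3.30. MTRNR2L1 (chromosome 17, 22022437 to 22023991) had 46.6 and 370 FPKM, MTRNR2L6 2.39 and 24.6 FPKM, MTRNR2L2 45.6 and 268 FPKM, and MTRNR2L8 63.5 and 271 FPKM. As copies of one sequence they can share reads. Under the same limit, the largest differences in the other direction were those of PSMA3, a proteasome subunit gene, with 18.6 and 2.56 FPKM (log2 difference -2.46), CLEC2D with 49.2 and 8.40 FPKM, FAM216A with 79.4 and 20.5 FPKM, SPARCL1 with 84.4 and 23.5 FPKM and TTLL7 with 18.3 and 4.73 FPKM. Exons of CLEC2D overlap the pseudogene NPM1P7 on the same strand and those of FAM216A overlap GPN3 on the other, so reads of these neighbours may be included.

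**Figure D3:**
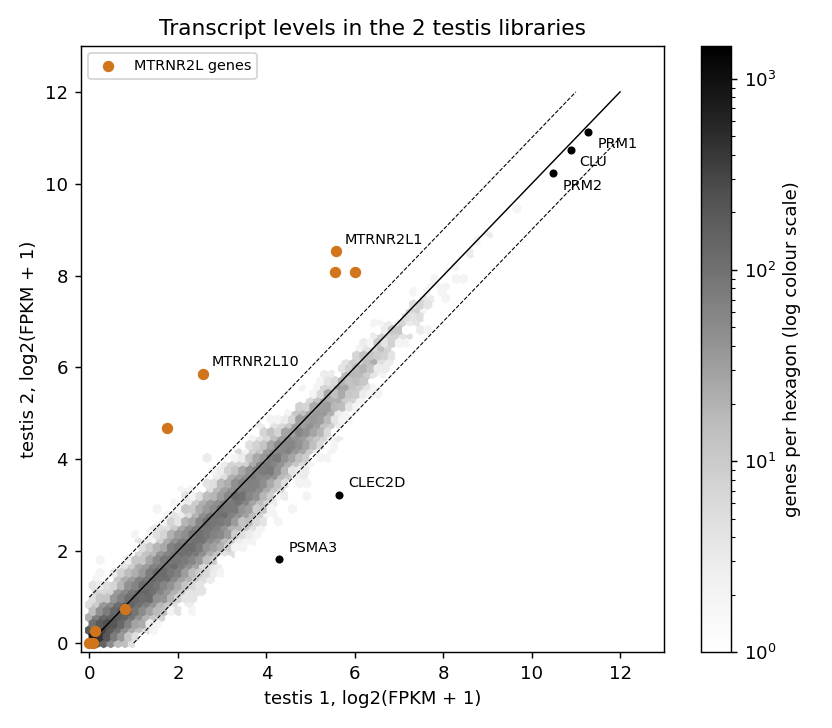
Transcript levels in both libraries. The axes are log2(FPKM + 1) in testis 1 and testis 2, hexagons are shaded by the number of genes on a log colour scale, black points are labelled genes, orange points the MTRNR2L genes, the solid line marks equal levels and the dashed lines a 2-fold difference. The 5 MTRNR2L genes above 1 FPKM lie above the upper dashed line, with MTRNR2L1 at 46.6 FPKM in testis 1 and 370 FPKM in testis 2.

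Of the 22 lists, 2 shifted between the libraries beyond the central 95% of random lists matched on level. By chance 1.1 are expected if list members vary independently, and more if members of a list vary together. Ribosomal protein genes had a median log2 difference of 0.02, which is 0.20 above the median of genes with a mean of at least 1 FPKM, at percentile 100, and 55 of 79 members lay above that median. Undifferentiated spermatogonia genes had a median of 0.04, at percentile 98.2; this list was at percentile 94.8 once the trend with GC content was removed. Meiotic spermatocyte genes, with a median of -0.30, lay at percentile 5.59, but outside the central 95% (0.70 to 1.99) under both other pseudocounts, with only genes of at least 1 FPKM and under both scalings, so the count of 2 depended on these choices.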

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

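The GC correction was chosen after the result was seen. The correlation between libraries moved from 0.980 to 0.971 with a pseudocount of 0.1 FPKM, to 0.943 with 0.01 FPKM and to 0.964 with only genes of at least 1 FPKM (the cause was not tested). Genes reaching the limit in both libraries numbered 19427 at 0.1 FPKM and 4165 at 10 FPKM in place of 13783 at 1 FPKM, 18092 after scaling to equal sums, and 14234 to 14752 with 1 library alone. Genes at least 2-fold higher and lower in testis 2, 76 and 290, numbered 212 and 737 with a pseudocount of 0.1, 239 and 826 with 0.01, 20 and 93 among genes of at least 10 FPKM, 587 and 615 after scaling to equal sums, and 149 and 142 after scaling to a median difference of 0 (a factor of 1.17 for testis 2). The scaling to equal sums multiplies all values, so the pseudocount of 1 weighs less there. The count of lists shifted between libraries was 4 in place of 2 with only genes of at least 1 FPKM, which added the meiotic spermatocyte and erythroid lists, and 1 once the GC trend was removed, which left the ribosomal proteins. The meiotic list, inside the central 95% as deposited, lay outside it under both pseudocounts, the limit of 1 FPKM and both scalings (percentiles 0.70 to 1.99). The ratio of X-linked to autosomal medians was 0.570 without the limit of 1 FPKM, and 0.677 to 0.704 with 1 library alone. The counts of lists above the 95th and below the 5th percentile and of paralog calls stayed within 1.5 times their values under the alternatives run, of which the scalings and the averaging of rows could not move the list counts: 12 lists above became 9 with only genes of at least 1 FPKM, as the piRNA, ion transport and macrophage lists lost their place, and 11 with random lists from genes above 0 (11 also in 15 of 20 further sets of draws), and the 12 germline and 11 somatic calls ranged from 11 to 12. With only genes of at least 1 FPKM the 3 lists below the 5th percentile (prostate and seminal vesicle, lymphocytes and mast cells, other tissues) no longer lay there, and 2 different ones did, endothelial cells and X-linked cancer-testis antigens; this setting removes the low members of each list. All 10 genes named for their difference between libraries kept its direction and a difference above 2-fold under both pseudocounts and both scalings. As they were picked for the largest differences, these settings could not have changed that outcome. List medians moved by more than the SD between libraries for all 22 lists under scaling to equal sums, which multiplies every value, for 13 with only genes of at least 1 FPKM and for 7 under scaling to a median difference of 0. The other alternatives could not move them by that measure. Averaging rows of the same symbol touched almost no gene and tests nothing. No paired analysis was possible because there is only 1 group. Depth limits statements on genes below about 0.17 FPKM at a length of 1.5 kb, where testis 2 has 3 reads.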

Other observations

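Gene families chosen after the data were seen, a few of whose members the lists also hold, varied widely. All 24 SPATA genes in the table reached 1 FPKM in both libraries and 14 reached 10 FPKM, with SPATA8 at 137 and 125 FPKM in testis 1 and testis 2. All 5 TSSK kinases, which act in spermatids, reached 1 FPKM, with TSSK6 at 50.98 and 53.7 FPKM and TSSK2 at 25.3 and 24.2 FPKM. Of 40 beta-defensin genes 11 reached 1 FPKM, with DEFB123 at 37.9 and 26.8 FPKM and DEFB126 at 33.7 and 30.7 FPKM. Only 6 of 370 protein-coding olfactory receptor genes did, and OR2H1 was highest with 3.75 and 2.78 FPKM. Among long non-coding RNA genes, LINC00467 had 436 and 448 FPKM, the imprinted H19 244 and 267 FPKM and MALAT1 85.3 and 66.7 FPKM.

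All the tests reported here were chosen after the pattern they address was seen, and that on genes with at least 1000 estimated reads after its own result; the test on sequence windows replaced an earlier version before it was run. The 5 MTRNR2L genes above 1 FPKM were higher in testis 2 by 2.08 to 3.30 on the log2 scale, and as both libraries come from the same kind of RNA, no biological explanation was tested. The GC trend across all genes was too small to account for these differences. Its median log2 difference ran only from -0.31 at the lowest GC content to -0.04 at the highest. For the 3 MTRNR2L genes with a transcript sequence and at least 1 FPKM, the median was 2.96 before and 3.08 after the trend was removed. Removing so small a trend could not have changed that outcome, so a GC effect particular to these genes was not tested. A candidate explanation is that reads of the mitochondrial 16S rRNA, left in different amounts by amplification of unfractionated RNA, were counted on its nuclear copies. The lowest share of 51-base windows within 2 mismatches of that rRNA was 6.73% among the genes that were higher in testis 2 (MTRNR2L6) and 3.30% in MTRNR2L3, picked for comparison because it was not higher (0.738 and 0.672 FPKM), a difference of 3.43 percentage points. This rests on 4 genes, a test on mitochondrial mRNA copies was dropped because none could be measured, and the ratio was highest in MTRNR2L10 (11.6) and not in the most similar, MTRNR2L1 (7.94), so the explanation stays a hypothesis.

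The spread between the libraries was set against counting noise. Only genes with 1 annotated transcript were used, with read limits set on testis 1 and lower minimums in testis 2. Over 1325 genes with at least 10 estimated reads, the between-library spread was 1.77 times its Poisson error. Over 77 genes with at least 1000 reads, the spread was 3.91 times that error. The first ratio lay between the bounds set for and against counting noise, and the second lay beyond the bound against it. For those 77 genes, an observed SD of 0.204 against a Poisson SD of 0.0562 argues against independent read counting as the only source. With 1 library on each side and counted mates not independent, the ratios do not divide the spread between counting noise and preparation. The share of counting noise stays open. GC content followed the difference across genes (Spearman's rho 0.247, genes not being independent), from a median of -0.31 in the genes up to the 10th percentile of GC content to -0.04 in the same number at the highest GC content, but with the trend removed 327 genes differed 2-fold in place of 366, 10.7% fewer; transcript length did not (rho -0.02, 0% fewer). What remains may come from the amplification of the cDNA, which was not tested.

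Muscle transcripts among the control genes were followed up. With ACTA1 at 13.8 ± 0.982 FPKM (SD, n = 2), 4 of 9 other abundant skeletal muscle transcripts reached the bound of 3.46 FPKM set from its level: MB with 6.94 ± 0.194 FPKM, TNNC1 with 5.81 ± 2.76 FPKM, TNNT1 with 5.42 ± 0.550 FPKM and MYBPC1 with 4.17 ± 0.677 FPKM. MYLPF had 0.770 ± 0.494 FPKM, MYL1 1.22 ± 0.128 FPKM and ATP2A1 1.44 ± 0.118 FPKM. A small share of skeletal muscle tissue in the RNA could bring such transcripts, but 4 of 9 lies between the bounds set for and against it, so it cannot be told apart from low expression in testis cells.

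The estimated depth rests on steps whose meaning, single mates or fragments, is not known. Parity was taken over genes with 1 transcript shorter than 2.5 kb at any FPKM, with values within 0.1 reads of 1 to 10 whole reads, a wider set than that of the depth estimate. In testis 1 they were even in 55.3% of 365 values (95% Wilson interval 50.2 to 60.4%), and 94 values stood at 2 reads against 58 at 1 read. In testis 2 they were even in 40.4% of 455 values (36.03 to 45.01%), with 92 at 2 reads and 156 at 1 read. Below 0.5 FPKM the shares were 55.1% of 321 and 36.7% of 381 values.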
